A study of Pimephales promelas with 31 samples.

How the data were processed

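Total RNA from female gonads was labelled with Cy3 and hybridised to one-colour Agilent arrays of 15208 non-control probes, 1 array per sample, per the labels' protocols. The authors deposited 1 scanner output file per array, whose processed signal, mean signal and background columns are intensities on a linear scale, together with a table of normalized log2 values for the series. The scanner files were made with Feature Extraction 10.1.1.1 per the file headers, while the submitters' processing notes name Feature Extraction 9.5. The deposited log2 table was compared with the scanner files: each column followed the log2 processed signal of its own array with a slope of 1 and a residual SD of 0. It thus differed from the scanner values by a constant per array. Spots marked as outliers in the scanner files were empty in it, 9 probes were absent from it, and its column medians over non-control probes ran from 0.0574 to 0.0983. The constant lay within 0.0155 of each array's median log2 signal over all spots without outlier marks, controls included, and values rose with signal.

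For the main analysis the log2 of the processed signal was taken and the 75th percentile of each array's non-control probes was subtracted. Control spots were left out and spots marked as non-uniform or population outliers, between 3 and 348 per array, were set to missing. No non-control spot was saturated, and all 31 arrays were within range in the scanner software's quality summary. Probes well above background on at least 7 of 31 arrays were kept, which left 14410. All 31 arrays were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. This design, the choice of comparisons and most alternatives were fixed before the data were examined. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.27 for indomethacin versus control.

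The rule set in advance for named genes required a gene name. All 15208 probes carry an unknown description and a contig or sequence-tag name, and 0 of these matched the reference table of 64593 genes. The 17 gene lists with 328 labels that had been fixed in advance, and the tests of them, were therefore not run. At most 2 higher and 2 lower probes were named by smallest p instead.

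The same steps were tested on simulated data made for indomethacin versus control from the fitted means and spreads of 14410 probes, with 50 probes changed at each of 4 sizes. Of 50 probes, 2 were recovered at a log2 change of 0.5, 27 at 1, 40 at 2 and 48 at 3, with 4 false calls. Each simulated value was drawn independently, so these arrays held no correlation between probes and no brightness or slide structure. The recovery and false calls therefore do not carry over to the real arrays, whose probes vary together. Alternatives covered normalization, background correction (normexp with an offset of 50), the authors' table, the filter on dim probes, outlier spots, slide, replicate number, array weights, the variance prior, the arrays fitted and the threshold. The settings of leaving out dim arrays, leaving out each slide and brightness as a covariate were chosen after the data were seen. Array brightness relative to spike-ins was the log2 75th percentile minus the array's mean deviation over 7 of the 10 spike-in probes, those with a median log2 signal above 8. The dim arrays were the 5 on which this value was below that of every control array. Slides were read from the file headers, and all arrays were scanned on 1 day.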

Results

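Ovarian gene expression was measured in sexually mature female fathead minnows (Pimephales promelas), a small North American fish widely used in ecotoxicology, after 96 h in control water or in water containing 1 of 3 cyclooxygenase inhibitors. Cyclooxygenases carry out the first committed step of prostaglandin synthesis, and prostaglandins act in ovulation and spawning in fish. Indomethacin was given at 100 µg/L, ibuprofen at 200 µg/L and celecoxib at 20 µg/L. Indomethacin and ibuprofen inhibit both cyclooxygenases, whereas celecoxib is selective for the inducible form. The series contained 31 one-colour arrays, with 8 arrays each for control, indomethacin and ibuprofen and 7 for celecoxib. Each group was spread over 4 slides, with 2 arrays of every group on each slide except that slide 4 held 1 celecoxib array. Each array carried 15208 different 60-base probes, of which between 11301 and 14606 per array were well above background. The 75th percentile of the processed signal ranged from 973 to 5620 between arrays. The labels do not say how the fish were housed, so the p-values measure the spread between these samples only.

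The array files and the reference table paired no probe with a gene, so the probes are given by identifier and sequence. Their genomic positions, the cyclooxygenase genes and the gene sets for prostaglandin, steroid and oocyte pathways were not analysed here. At most 2 probes that were higher and 2 that were lower are named, chosen after their values were seen as those with the smallest p in indomethacin versus control.

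The comparison of indomethacin with control asked which ovarian transcripts differ in females exposed to this inhibitor. At a limma adjusted p under 0.05, 1 probe, UF_Ppr_AF_113674, was lower in indomethacin females, and no probe was higher. Its sequence is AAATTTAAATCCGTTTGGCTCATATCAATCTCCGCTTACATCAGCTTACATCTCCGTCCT. Its level, in log2 units relative to the 75th percentile of each array, was -4.65 ± 0.60 (SD, n = 8) in control and -6.13 ± 0.53 (SD, n = 8) in indomethacin females. The log2 fold change was -1.48 ± 0.24 (SE), a 2.78-fold lower signal, with a limma adjusted p of 0.0111 over 14410 probes. All 8 indomethacin arrays were below the control mean and 7 were below every control array. The probe was dim, though marked well above background on all 8 control arrays and on 7 of the 8 indomethacin arrays. Its processed signal ran from 50.7 to 282 on control arrays. On indomethacin replicates 2, 6, 7 and 8 it was 16.3, 15.1, 18.2 and 14.3, close to background. On the other indomethacin arrays it ran from 41.7 to 72.1. The call did not hold in every setting. With normexp background correction the log2 fold change was -0.40 ± 0.18 (SE) with a limma adjusted p of 0.137. With the replicate block, array weights and only the groups compared it was -1.48, -1.44 and -1.48, with limma adjusted p-values of 0.0695, 0.0507 and 0.303. Without the 5 arrays that were dimmer against their spike-ins than every control array, the log2 fold change was -1.50 with a limma adjusted p of 0.343, and with array brightness as a covariate it was -1.30 with a limma adjusted p of 0.247. Within slides 1 to 4 the log2 fold changes were -1.27, -1.94, -1.97 and -0.73, and with slide as a fixed block the limma adjusted p was 0.0188.

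**Figure D1:**
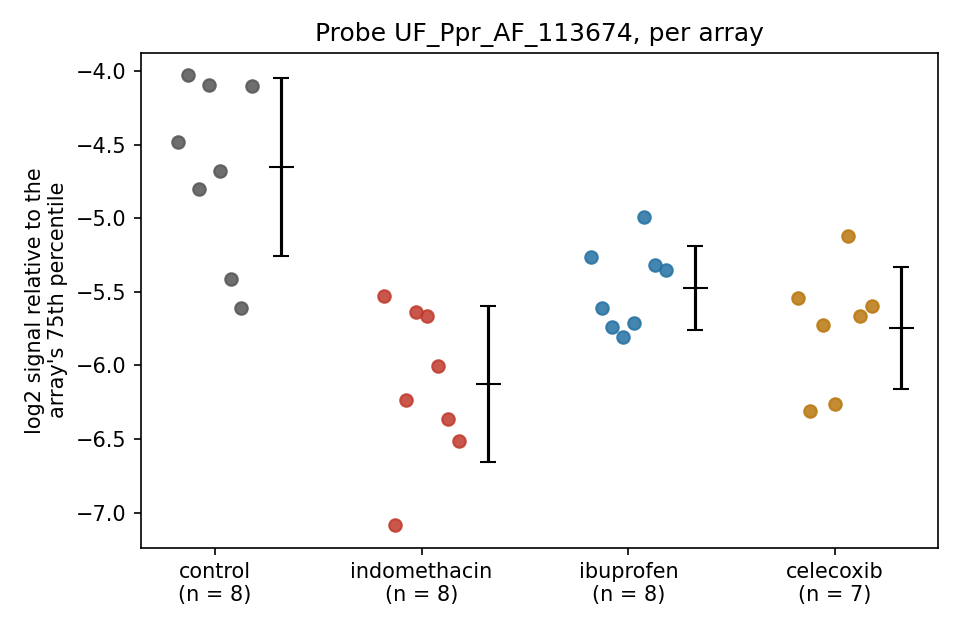
Level of probe UF_Ppr_AF_113674 on each array, as log2 processed signal relative to the array's 75th percentile (vertical axis), by exposure group (horizontal axis); points are arrays and bars show the mean and SD. Control arrays average -4.65, and the indomethacin, ibuprofen and celecoxib arrays average -6.13, -5.47 and -5.75.

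The other 3 named probes did not pass the test with all arrays. UF_Ppr_AF_116489 (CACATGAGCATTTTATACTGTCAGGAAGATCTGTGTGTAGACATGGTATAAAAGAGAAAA) had a log2 fold change of -1.07 ± 0.23 (SE), with levels of -4.47 ± 0.59 (SD, n = 8) in control and -5.54 ± 0.32 (SD, n = 8) in indomethacin. Its log2 fold change was -0.29 ± 0.17 (SE) with normexp and -0.18, -1.35, -1.53 and -1.23 within slides 1 to 4; without control replicate 3 it was -1.23 with a limma adjusted p of 0.0226. UF_Ppr_AF_115162 (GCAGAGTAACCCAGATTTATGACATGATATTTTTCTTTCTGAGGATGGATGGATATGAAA) had a bright signal, at 1.96 ± 0.26 (SD, n = 8) in control and 2.73 ± 0.29 (SD, n = 8) in indomethacin, a log2 fold change of 0.77 ± 0.17 (SE), with 0.75, 0.49, 1.06 and 0.77 within slides 1 to 4. Of the 8 indomethacin arrays, 7 were above every control array for this probe. UF_Ppr_AF_117213 (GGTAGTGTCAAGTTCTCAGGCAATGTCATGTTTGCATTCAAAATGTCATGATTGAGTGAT) had a log2 fold change of 1.07 ± 0.23 (SE) close to background, being well above it on 6 of 8 control and 7 of 8 indomethacin arrays. Within slides 1 to 4 it was 0.44, 1.45, 1.99 and 0.39, and without indomethacin replicate 5 it was 1.27 with a limma adjusted p of 0.00534. All 3 shared a limma adjusted p of 0.203 with all arrays.

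Beyond the single call, 2743 of 14410 probes had an unadjusted limma p under 0.05 in indomethacin versus control, where 720 would be expected with no difference. Of these, 1893 were higher and 850 lower in indomethacin females; with quantile normalization the counts were 1649 higher and 1127 lower, and with normexp 4146 higher and 474 lower. Without the 5 dim arrays the number was 604, of which 251 were higher, and with brightness as a covariate it was 633, of which 278 were higher. Leaving out indomethacin replicate 6 gave 1518, and leaving out indomethacin replicate 8 gave 1780. These were the 2 dimmest arrays against their spike-ins, at 8.98 and 10.02 log2, and both were on slide 3. Slide 3 alone gave 3140 such probes, and slides 1, 2 and 4 alone gave 414, 652 and 416. In a setting chosen after the data were seen, leaving out slides 1 to 4 in turn gave 3079, 1513, 787 and 3001 such probes, and no probe passed the limma threshold without slide 2 or without slide 3. In an exact permutation test on the distance between group means over all probes, chosen after the data were seen, the two-sided p for indomethacin versus control was 0.0584, or 0.320 after Benjamini-Hochberg adjustment over 6 pairs of groups.

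**Figure D2:**
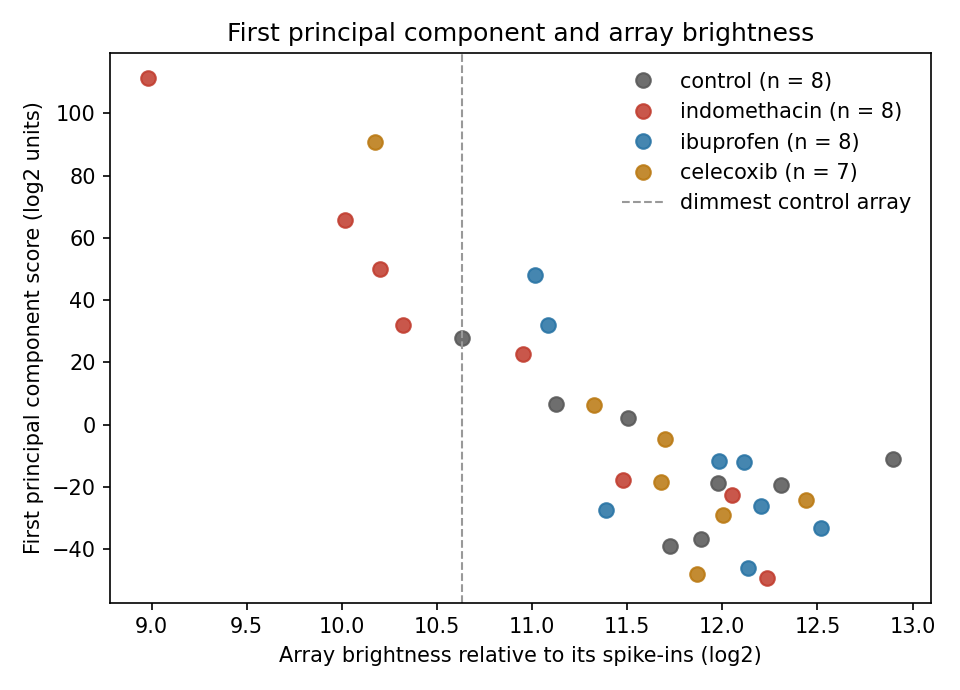
Score of each array on the first principal component of the log2 levels (vertical axis) against the array's brightness relative to its spike-in controls in log2 units (horizontal axis); each point is an array, coloured by group, and the dashed line marks the dimmest control array. Of the 5 arrays left of the line, 4 are indomethacin and 1 is celecoxib.

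Array brightness was compared between the groups, and no difference passed adjustment. Relative to the synthetic transcripts added to each labelling reaction, the log2 75th percentile was 11.76 ± 0.70 (SD, n = 8) on control, 10.78 ± 1.11 (SD, n = 8) on indomethacin, 11.81 ± 0.56 (SD, n = 8) on ibuprofen and 11.60 ± 0.72 (SD, n = 7) on celecoxib arrays. The indomethacin difference from control was -0.98, with a two-sided exact permutation p of 0.0521 and an adjusted p of 0.312 over 18 tests of array measures. By slide the difference was -0.09, -0.78, -2.81 and -0.23 on slides 1 to 4. Over all slides the log2 75th percentile alone differed by -0.63 and the spike-in mean by 0.35. On slide 3 the spike-ins also added to the difference. Their mean log2 deviation there was 0.95 and 0.33 on indomethacin replicates 6 and 8, against 0.08 and -1.13 on control replicates 1 and 8.

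Brightness ran along the main axis of variation among the 31 arrays. The first principal component held 21% of the variance, and its Pearson r with brightness was -0.89 (Spearman rho -0.78; permutation p of 1e-05 for both, the smallest that the resamples could give; adjusted p 1.5e-05 over 3 relations). Without the 2 arrays farthest from the median brightness, r was -0.82. The sign of a principal component is arbitrary. The relation is partly built in, because brightness contains the same array percentile that was subtracted from every level. A signal that stays near background therefore falls in level as that percentile rises. How much of r comes from this was not tested, and the permutation p does not allow for it. Within groups, r was -0.61 over control, -0.99 over indomethacin, -0.81 over ibuprofen and -0.92 over celecoxib arrays, with exact permutation p-values of 0.109, 2.48e-05, 0.0144 and 0.0145. The relation within ibuprofen rested on 2 arrays, since r was -0.18 without them. Within slides 1 to 4, r was -0.84, -0.97, -0.90 and -0.88.

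The comparison of ibuprofen with control found no probe past the limma adjusted p threshold of 0.05. At an unadjusted p under 0.05 there were 328 probes, 167 higher and 161 lower, fewer than the 720 expected. Such a count was ordinary for these arrays. Of 100 splits of the control and ibuprofen arrays, 78 gave as many, the real one included, and the median of the others was 443. The direction depended on the processing, with 298 higher and 101 lower after median centring and 323 higher and 93 lower in the authors' table. The balance went the other way with quantile normalization, at 142 higher and 197 lower, and with normexp, at 52 higher and 149 lower. Array weights gave 680 such probes and normexp 201, and still none past the threshold. For 75.4% of the 14410 probes the 95% interval of the log2 fold change lay within 1 log2 unit of 0, which excludes a larger change for those probes taken singly. UF_Ppr_AF_113674 was at -5.47 ± 0.29 (SD, n = 8), a log2 fold change of -0.82 ± 0.24 (SE) with a limma adjusted p of 0.9999, and all 8 ibuprofen arrays were below the control mean. The log2 fold change was -0.56 with normexp and -0.44, -1.30, -1.27 and -0.27 within slides 1 to 4. The probe was selected on its difference from these same 8 control arrays, which all 3 comparisons share, so its values for ibuprofen and for celecoxib are not independent of that selection.

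The comparison of celecoxib with control also found no probe past the limma threshold. At an unadjusted p under 0.05 there were 513 probes, 132 higher and 381 lower, fewer than the 720 expected. Of 100 splits of the control and celecoxib arrays, 42 gave as many, the real one included. The balance was 258 higher and 283 lower with median centring, 222 and 315 with quantile normalization and 231 and 301 in the authors' table. Array weights gave 976 such probes, 252 higher and 724 lower, and normexp gave 299, with none past the threshold in either. Without the 1 dim celecoxib array and the 4 dim indomethacin arrays there were 716. The 95% interval lay within 1 log2 unit of 0 for 72.2% of probes. UF_Ppr_AF_113674 was at -5.75 ± 0.42 (SD, n = 7), a log2 fold change of -1.09 ± 0.25 (SE) with a limma adjusted p of 0.899, and all 7 celecoxib arrays were below the control mean. The log2 fold change was -0.56 with normexp and -0.53, -1.59, -1.40 and -0.81 within slides 1 to 4.

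The 3 inhibitors were then compared with each other, at concentrations that differ between drugs. Indomethacin is an indole acetic acid, ibuprofen an arylpropionic acid and celecoxib a diarylpyrazole sulfonamide. No probe differed between indomethacin and ibuprofen, between indomethacin and celecoxib or between ibuprofen and celecoxib at a limma adjusted p under 0.05. At an unadjusted p under 0.05 there were 2238, 1508 and 619 probes in that order, where 720 would be expected with no difference. Without the 5 dim arrays there were 756, 484 and 832. Of 100 splits of the arrays of each pair, 11, 23 and 37 gave as many as the real groups, the real one included. These counts therefore do not exclude chance. Indomethacin versus ibuprofen gave 1361 without indomethacin replicate 6 and 4861 with normexp. Indomethacin versus celecoxib gave 741 without indomethacin replicate 6, 3713 without celecoxib replicate 4 and 3151 with array weights. Ibuprofen versus celecoxib gave 328 with normexp and 1042 with array weights, which called 4 probes. The 95% interval of the difference lay within 1 log2 unit of 0 for 63.0%, 61.9% and 72.9% of probes, so differences larger than this remained possible for the rest. UF_Ppr_AF_113674 differed by -0.66 ± 0.24 (SE) log2 between indomethacin and ibuprofen (limma adjusted p 0.246) and by -0.38 ± 0.25 (SE) between indomethacin and celecoxib (limma adjusted p 0.494). The direction of both differences reversed with normexp, where the log2 fold changes against control were -0.40 for indomethacin, -0.56 for ibuprofen and -0.56 for celecoxib. The normexp offset compresses dim signals, and whether it produced this reversal was not tested. The moderated F test over the 4 groups passed no probe after adjustment, with 1494 probes at an unadjusted p under 0.05. That number was 809 without indomethacin replicate 6, 2515 without celecoxib replicate 4 and 670 without the 5 dim arrays. Of 100 splits of all 31 arrays, 10 gave 1494 or more such probes, the real one included.

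The log2 fold changes of the 3 drugs against the shared controls were correlated across probes, which are not independent replicates. Over 13651 probes with a value on every array, r was 0.42 for indomethacin and ibuprofen, 0.40 for indomethacin and celecoxib and 0.30 for ibuprofen and celecoxib. Simulated groups with no drug effect against shared controls gave mean r values of 0.51, 0.48 and 0.51, and in 71, 64 and 89 of 100 simulations r was as high as observed. The covariances were 0.0625, 0.0701 and 0.0341, against simulated means of 0.0726, 0.0671 and 0.0743. When the controls were split into 2 sets of 4, the median r over 70 splits was 0.03, 0.04 and -0.12. The simulated r values spread widely, from 0.04 to 0.82, from -0.08 to 0.86 and from -0.01 to 0.82 for the 3 pairs. No response shared between drugs was detectable beyond the one that shared controls produce. With such a spread a shared response could have been missed, so its absence is not shown. No overlap of calls could be formed because ibuprofen and celecoxib had none.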

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

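The tests of brightness as a covariate and of leaving out dim arrays, sets of 4 arrays or each slide in turn were chosen after the excess of probes in indomethacin versus control had been seen, and slide 3 was singled out after its own count had been seen. For brightness, the dim arrays and slide 3, the outcome that would count against each was set before the test was run. Slide as a fixed block was planned, but its expected outcome was set after its result had been seen. Among 40 groups of values tested for a sample far from the rest, 4 were found, where about 2 arise by chance. Control replicate 3 had 11301 probes above background, against 12905 on the next lowest control array. Celecoxib replicate 4 had a first principal component score of 90.9, against 6.41 on the next celecoxib array. A further measure took each probe's difference from its mean log2 level over control arrays. The median over other probes was then subtracted from the median over probes with rc in their target name. Celecoxib replicate 4 had a value of -0.24 in this measure, against -0.04 on the next celecoxib array. It is the dim celecoxib array, on slide 3, and both measures tracked brightness, so its 2 flags are not independent. Probe UF_Ppr_AF_117213 was at -6.53 on control replicate 7, against -7.22 on the next control array.

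The first pattern is the excess of probes at an unadjusted p under 0.05 in indomethacin versus control, 2743 of 14410. Of 100 splits of the 16 arrays into 8 and 8, 6 gave as many, the real one included, the highest other split giving 3502, so chance cannot be excluded. These splits, and those described below, were not balanced over the slides as the real groups are. A test of splits within slides was not run. A shift shared by all arrays of a slide cancels from this difference, because both groups have 2 arrays on every slide, so the design excludes it as the source; the 3009 probes found with slide as a fixed block add no test of it. A difference between the groups within slide 3 stays open and could account for the excess: without slide 3, 787 probes had such a p, against 3079, 1513 and 3001 without slide 1, 2 or 4. Slide 3 also held the largest difference in brightness, -2.81 log2 between indomethacin and control, so slide 3 and brightness cannot be told apart here. Array brightness could account for the excess: with brightness relative to the spike-ins as a covariate 633 probes had such a p, and without the 5 dim arrays 604 had. Both are below the 720 expected with no difference, but above the median of 492 over the other splits of all 16 arrays. Over all 70 ways of leaving out 4 of the 8 indomethacin arrays, the count ran from 352 to 5922. It was 486 when the 4 dim arrays were left out and 5922 when the other 4 were, so the fall is not one of sample number alone. By definition no control array could be dim. Over the indomethacin arrays, brightness ranked exactly against the first principal component (Spearman rho -1), so the dim arrays lay farthest along it. Leaving them out, or adjusting for brightness, could lower the count under a drug effect as well. The fall therefore does not tell brightness from a drug effect. Whether the dimness is technical or itself follows from indomethacin was not tested.

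For the 1 probe past the threshold in indomethacin versus control, 5 of 100 splits gave at least 1 probe, the real one included, the highest other split giving 28, so chance is not excluded. Ibuprofen versus control and celecoxib versus control gave 0 probes, a result that all 100 splits equal by construction, with highest other splits of 12 and 115. The same holds for indomethacin versus ibuprofen, indomethacin versus celecoxib, ibuprofen versus celecoxib and the F test over the 4 groups, where all 100 splits reached 0 or more and the highest other splits gave 1366, 4930, 137 and 2 probes. Any call at all came from 2 of the other splits for indomethacin versus ibuprofen and from 10 for indomethacin versus celecoxib. Splits that call 1366 or 4930 probes while the real one calls 0 point to a structure among the arrays.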

How the results depend on the processing

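Leaving out the 5 dim arrays, leaving out each slide and using brightness as a covariate were chosen after the data were seen. The 1 probe called in indomethacin versus control became 0 with normexp background correction, probes well above background on all 31 arrays (which drops the called probe), the replicate block, array weights, only the groups compared, each slide alone, without slide 2 or 3, without the dim arrays and with the brightness covariate; it was 1 in the 11 other settings. The called probe's log2 fold change ran from -1.97 to -0.40 over the settings other than leaving out a slide and its limma adjusted p from 0.00960 to 0.9999; the smallest fold came with normexp, whose offset compresses dim signals, and the cause of the other losses was not tested. With each of 16 arrays left out it stayed past the threshold, at limma adjusted p-values of 0.00150 to 0.0481. Slide as a fixed or a random block left every count of calls as it was. Replicate numbers did not pair the samples; the median correlation of deviations from the group means was -0.01 for 45 same-numbered pairs and 0.00 for 315 others. The replicate block gave a smallest limma adjusted p of 0.0695 and changed no other call; 2 of 31 arrays matched their own number best. Array weights called 4 probes in ibuprofen versus celecoxib; the cause was not tested. Slide 1 alone gave 1 probe for ibuprofen versus control, 3 for celecoxib versus control, 1 for indomethacin versus celecoxib, 1 for ibuprofen versus celecoxib and 1 for the F test, and slide 2 alone gave 1 each for ibuprofen versus control, indomethacin versus ibuprofen, ibuprofen versus celecoxib and the F test, with 2 arrays per group. Leaving out 1 array gave 1 to 2 probes for indomethacin versus control (2 without control replicate 3 or indomethacin replicate 5), 0 to 1 for indomethacin versus ibuprofen (1 without ibuprofen replicate 3 or indomethacin replicates 4 or 5), 0 to 2 for ibuprofen versus celecoxib (2 without ibuprofen replicate 3), 0 to 1 for the F test (1 without control 6 or 7 or indomethacin 5) and 0 for the other 3 comparisons. Counts at an unadjusted p under 0.05 moved more: normexp gave 4620 for indomethacin versus control, 4146 of them higher, and 4861 for indomethacin versus ibuprofen. With 1 array left out, indomethacin versus celecoxib ran from 741 to 3713, without indomethacin replicate 6 and celecoxib replicate 4. The correlation between drugs moved to 0.033, 0.039 and -0.117 when the controls were split, which removes the shared arrays by construction. Gene list tests were not run. Signal limits the dim probes: 10333 of 15208 were well above background on all arrays.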

Other observations

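All tests in this part were chosen after the data had been seen. Among the 600 most variable probes, 115 formed the cluster with the most members, with a median pairwise Pearson r of 0.83 across arrays. Their mean log2 level ran from -2.89 on indomethacin replicate 4 to 3.96 on celecoxib replicate 7 relative to the mean of 31 arrays. Only 44 of the 115 were well above background on all 31 arrays, so the lower levels lie partly at background and the range is not a fold change. The level was 0.24 ± 2.08 (SD, n = 8) in control, -0.51 ± 1.71 (SD, n = 8) in indomethacin, -0.60 ± 2.16 (SD, n = 8) in ibuprofen and 0.999 ± 2.80 (SD, n = 7) in celecoxib females.

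Technical sources of this set were weighed. Printing position is argued against by the 827 kept non-member probes next to a member, whose median r with the set was -0.064, against -0.056 for all other probes. The distance between members did not decide the question. Its median was 5.10 spot positions to the nearest other member, against 5.66 in random sets. Members thus lay closer together than in most random sets, whose 2.5th and 25th percentiles were 5 and 5.39. Brightness as the main source is also argued against, since its Pearson r with the set was -0.36 over 31 arrays (Spearman rho -0.38, permutation p-values 0.0466 and 0.0336), and -0.43 without the 2 arrays farthest in brightness. Drug exposure remains open, with a permutation p of 0.468 for the 4 groups and 0.0873 of the variance between groups. The set may reflect a difference in ovarian state between fish, a hypothesis that no label or gene name here can test.

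Of the next 3 clusters, one of 12 probes averaged -1.31 ± 0.58 (SD, n = 7) in celecoxib and 0.67 ± 1.54 (SD, n = 8) in control females, a difference of -1.98 log2 with 7 of 7 celecoxib arrays below the control mean. Its two-sided exact permutation p was 0.00606, and the Benjamini-Hochberg adjusted p over 12 tests was 0.0727, so it did not pass.

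Of 13651 probes searched, 58 had 2 distinct levels at least 3 log2 units apart with 2 or more arrays on each side. One of them was also among the 115. They formed 55 different patterns over the arrays. The widest gap was 9.81 log2 units, in a probe not well above background on control replicate 4 and indomethacin replicate 8 and well above background on the other 29 arrays. Another probe had 18 arrays at the upper level, 5 control, 5 indomethacin, 5 ibuprofen and 3 celecoxib, and was not well above background on any of the 13 others. For both probes the lower level is background, so the size of the gap is not a measured difference in expression. This was not so for every probe of the 58. In a further probe all 15 arrays at the lower level were well above background, with a gap of 3.60 log2 units. In another all 18 were, with a gap of 3.06.

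Probes with rc in their target name, whose meaning the files do not give, tracked array brightness. Each probe's log2 level was first expressed as a difference from its mean over control arrays. The median difference over the 3096 probes with rc in their name, minus that over the 11314 others, was then compared with brightness. Its Pearson r with brightness was 0.90 over 31 arrays (Spearman rho 0.79, permutation p of 1e-05 for both, the smallest possible, and adjusted p 1.5e-05 over 3 relations). It was 0.83 without the 2 farthest arrays, and 0.69, 0.90, 0.95 and 0.86 within slides 1 to 4, although the value on slide 2 was -0.04 without its 2 farthest arrays. Within control, indomethacin, ibuprofen and celecoxib arrays r was 0.78, 0.99, 0.80 and 0.81, with exact permutation p-values of 0.0242, 2.48e-05, 0.00930 and 0.0609. Without the 2 farthest arrays of each group these were 0.51, 0.97, 0.22 and 0.81, so within ibuprofen the relation rested on 2 arrays. As with the first principal component, brightness contains the percentile subtracted from every level, so part of this relation may be built in. How much was not tested, and the permutation p-values do not allow for it.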
